A study of Mus musculus with 13 samples.

How the data were processed

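Total RNA of 20 mg of snap-frozen lung or mammary tumor was made into libraries from 100 ng with a kit that removes ribosomal RNA and sequenced on a NextSeq500 with single reads of 75 bp, per the labels. Fragmentation depended on the RNA quality of each sample, which is not given per library in the sources used here. Met1 cells, 250000 per mouse, were injected at 8 weeks of age and tissue was taken 2 weeks later. The submitters' processing notes name Salmon, without a version, DESeq2 1.18.1 and the genome build mm10. The values used here are the estimated counts (expected counts) and the TPM deposited by the authors, in 1 table each for 13 libraries. The ratio of count to TPM was constant between libraries but for 1 factor per library, with a largest deviation of 1.02e-14 on the log2 scale over 10558 genes, so the deposited counts are TPM scaled by an average gene length and by library, and they were rounded to whole numbers before fitting. The tables hold 46679 gene IDs and 0 columns of no sample; 46201 IDs were named from GENCODE M21, which is on GRCm38, and 478 kept their ID.

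Libraries held 8321037 to 13982903 estimated counts. A fold against a group with 0 counts is given as a bound from 3 counts over the group, and a fold against a group with 1 to 3 counts as a ratio with an exact 95% counting interval. Bounds and intervals cover counting error alone, since PCR reads without molecular identifiers are not independent molecules. CPM are counts relative to library sizes scaled by TMM factors, and log2 CPM used a prior count of 2.

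The mouse was the replicate. Groups were 4 normal lungs, 4 tumor-bearing lungs and 3 tumors; for the 2 normal mice with libraries of both batches the batch 1 library was used, and the batch 2 library entered as an alternative. edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr) under R 4.3.3 fitted group and preparation batch, with 8 lungs for tumor-bearing against normal lung and 11 libraries for both comparisons of tumors. The Benjamini-Hochberg threshold was 0.05. The other tools were voom of limma 3.58.1 and DESeq2 1.42.0, and limma on log2 TPM with a pseudocount of 1. The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

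Lists of genes, 42 in number, covered immune, epithelial, stromal and vascular cell types, signs of sample quality such as ribosomal protein, mitochondrial and histone genes, and pathways from interferon response to the cell cycle; lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Medians of lists also were computed with genes at 0 counts in a group set to their bound. Named genes are, among genes past the threshold with a mean log2 CPM of at least 0, an official name and groups that do not overlap, the 12 with the largest positive and the 12 with the largest negative change; with fewer than 5 past the threshold in a direction, the 5 with the smallest unadjusted p in that direction; and up to 4 members with the smallest p of each described list. A list score is the mean log2 CPM of its members relative to the mean of the 10 lung libraries, and scores were compared with exact permutations within batches.

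The numbers of tumors and lungs pair 3 mice. The correlations across genes of the residuals of these pairs were 0.179, 0.0355 and −0.133 for mice 6877, 6880 and 6881, and the fit with the mouse as a block is given as an alternative. The fits were tested on simulated data with the sizes of these groups: for tumor-bearing against normal lung edgeR found 40% of genes shifted by a log2 of 1 and 95% of those shifted by 2, with 8 of 16507 unchanged genes called, DESeq2 57% and 96% with 40 called, and voom 39% and 93% with 11 called. For tumors edgeR found 9% and 67% against tumor-bearing lung and 19% and 78% against normal lung. A simulated list of 20 genes shifted by a log2 of 0.5 was found by camera in all 3 comparisons. In the lung comparison its adjusted p was 0.201 with an estimated correlation and 0.0642 with fry, which both missed it. Simulated genes were drawn independently of each other. This cannot show how camera at the preset correlation behaves where the genes of a list vary together.

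Alternatives were other scaling factors and filters, other tools, fits without the batch term, other uses of the repeat libraries, each batch alone and leaving out each library of the main fit. Added after the data were seen were protein-coding genes alone, an offset for gene length and GC per library and, for the tumors, the batch 2 libraries alone. An offset by effective length was not run, because the constant ratio of count to TPM means that it would move nothing. Genes with a group mean log2 CPM below 0 were left out of the search for single libraries far from their group.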

Results

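RNA was sequenced from 13 libraries of female FVB mice aged 10 weeks: 6 libraries from the lungs of 4 mice without a tumor, 4 libraries from the lungs of 4 tumor-bearing mice, and 3 libraries from the mammary tumors of 3 of those mice. The tumors grew for 2 weeks from 250000 cells of the mouse mammary tumor line Met1 placed in the mammary fat pad. Preparation batch 1 held 2 normal and 3 tumor-bearing lungs. Batch 2 held 4 normal lungs, 1 tumor-bearing lung and the 3 tumors. Normal lungs 6886 and 6888 were prepared in both batches, and each of these mice was counted once. Libraries held 8321037 to 13982903 estimated counts.

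The share of protein-coding counts was 68.2 to 69.6% in the normal lungs of batch 1 and 49.0 to 59.0% in the tumor-bearing lungs of batch 1. It was 47.0 to 54.7% in the normal lungs of batch 2, 45.6% in the tumor-bearing lung of batch 2 and 46.5 to 51.8% in the tumors. Rn7s1, an RNA of the signal recognition particle, took 12.9 to 15.1% of the counts in the normal lungs of batch 1 and 5.55 to 10.3% in the tumor-bearing lungs of that batch, against 29.5 to 35.9% and 37.8% in batch 2. The gene models Gm12895 and Gm12896 together took 5.12 to 5.83% in the normal and 12.1 to 23.8% in the tumor-bearing lungs of batch 1, against 2.75 to 3.16% and 3.21% in batch 2. Gm26917 took 3.95 to 4.17% and 8.45 to 11.5% in batch 1, against 0.635 to 0.818% and 0.759% in batch 2. The identity of reads assigned to these gene models is uncertain where other copies of their sequence exist.

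**Figure D1:**
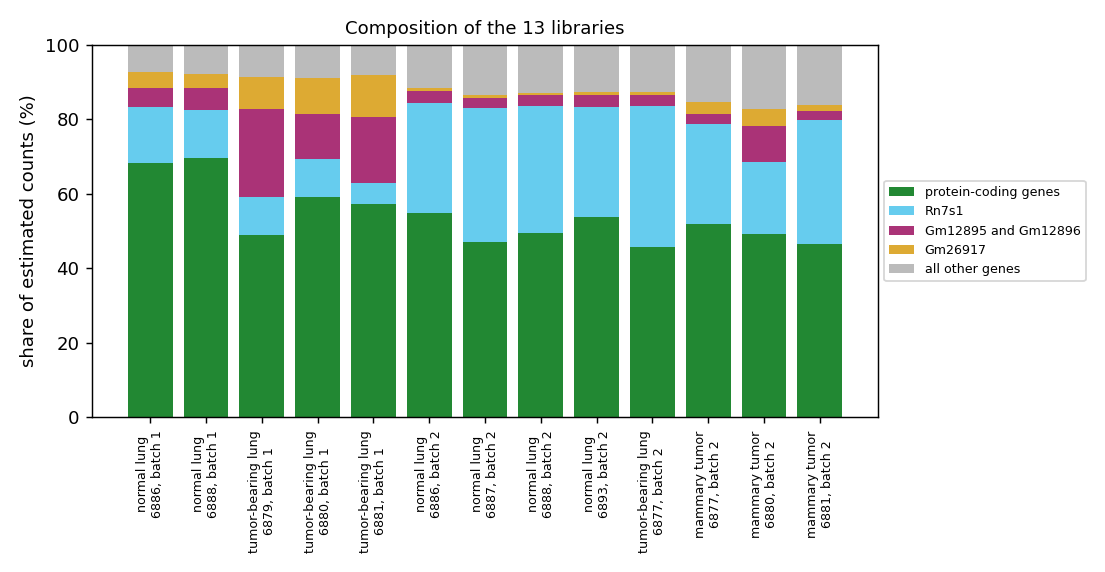
Share of all estimated counts (percent, vertical axis) taken by protein-coding genes, Rn7s1, Gm12895 with Gm12896, Gm26917 and all other genes in each of the 13 libraries. In batch 1 the protein-coding share was 49.0 to 59.0% in the 3 tumor-bearing lungs and 68.2 to 69.6% in the 2 normal lungs.

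The first comparison asks what a distal mammary tumor does to gene expression in the lung, the purpose the series states. In tumor-bearing lungs the immediate early transcription factors Fos and Egr1 rose, and Chordc1, a cochaperone of Hsp90, and Npr3, the clearance receptor of natriuretic peptides, fell. The calls of all 4 genes were lost without normal lung 6886, and also without tumor-bearing lung 6879, 6880 or 6881. Fos stood at 59.0 ± 16.3 CPM (SD, n = 4) in tumor-bearing and 13.2 ± 2.25 (SD, n = 4) in normal lungs, a log2 fold change of 2.03 (SE 0.23). Egr1 stood at 64.2 ± 18.7 against 17.5 ± 5.29 CPM (SD, n = 4 each), a log2 fold change of 1.66 (SE 0.16). Genes of neutrophils were higher as a group (median log2 fold change 1.23, n = 16 genes), and genes of ribosomal proteins, the mitochondrial genome and the unfolded protein response were lower as groups (medians −0.42, −0.50 and −0.41), in a test that presets the correlation between genes. These 4 group calls were lost with adjusted p = 0.526, 0.526, 0.690 and 0.526 with an estimated correlation.

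Chordc1 stood at 15.9 ± 2.49 CPM in tumor-bearing and 35.8 ± 7.46 in normal lungs (SD, n = 4 each) and fell by 1.27 on the log2 scale (SE 0.14). Npr3 stood at 73.7 ± 15.2 against 160 ± 44.1 CPM (SD, n = 4 each) and fell by 1.24 (SE 0.15). The other genes past the threshold were Gm15542, a processed pseudogene that fell by 1.99 (SE 0.22), and Gm26825, a lincRNA that fell by 1.46 (SE 0.18). Both are uncertain, since a processed pseudogene resembles its parent gene and Gm26825 overlaps an antisense pseudogene. On GRCm38, Fos lies on chromosome 12 at 85473890 to 85477273, Egr1 on chromosome 18 at 34859823 to 34864984, Chordc1 on chromosome 9 at 18292125 to 18317442 and Npr3 on chromosome 15 at 11839896 to 11907287. Gm15542 lies on chromosome 7 at 140890887 to 140892080 and Gm26825 on chromosome 5 at 5781530 to 5783636.

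Within batch 1 and batch 2 the log2 fold changes were 2.37 and 1.24 for Fos, 1.79 and 1.02 for Egr1, −1.30 and −1.37 for Chordc1, and −1.29 and −1.10 for Npr3. They were −1.97 and −2.04 for Gm15542 and −1.62 and −1.25 for Gm26825. The values of batch 2 rest on tumor-bearing lung 6877 alone, and normal mice 6886 and 6888 enter both batches. The values of the batches are therefore not independent, which also holds for the medians of lists within batches. The genes next in line did not pass the test over all genes. Among those with positive values were Nr4a1, an orphan nuclear receptor induced as an immediate early gene (1.64, SE 0.27, adjusted p = 0.112), the splicing factor Srsf5 (1.12, SE 0.16, adjusted p = 0.0910) and the endocytic protein Fcho1 (1.63, SE 0.26, adjusted p = 0.112). Those with negative values were Zbtb16, a transcription factor (−1.91, SE 0.25, adjusted p = 0.0638), Hlf, a clock output transcription factor (−1.20, SE 0.16, adjusted p = 0.0730), and Hspa8, the constitutive Hsc70 chaperone (−1.34, SE 0.20, adjusted p = 0.104).

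edgeR tested 16727 genes in 8 lungs and called 6, with adjusted p = 0.0306 for Fos, Egr1, Chordc1 and Gm15542 and 0.0380 for Npr3 and Gm26825. Of these 2 were higher and 4 lower, and 2342 genes had an unadjusted p below 0.05. DESeq2, with its own filter on 32303 genes, called 390 (127 higher, 263 lower), and on the 16727 genes of edgeR it called 399 (143 higher, 256 lower). edgeR without a filter called 275 of 32303. On the 16727 genes limma voom called 6, and limma on TPM called 90, of which 4 were higher and 86 lower. Within batch 1 alone 39 genes passed, 4 of them shared with the 6, and within batch 2 alone 8 passed, 0 of them shared, if its 1 tumor-bearing lung is taken to vary like the normal lungs. With repeats summed per mouse 2 passed, 1 of them shared, without a batch term 1, which was shared, and with the batch 2 library of the repeated mice 1, which was not. Across 17065 genes, which are not independent replicates, the log2 fold changes of the 2 batches had a Pearson r of −0.07. The count of edgeR was 0 without normal lung 6886 and 0 without tumor-bearing lung 6879, 6880 or 6881 (1512, 2027, 2158 and 2086 genes at unadjusted p below 0.05), 16 without normal lung 6887 and 221 without tumor-bearing lung 6877, the only tumor-bearing lung of batch 2. It was 4 without normal lung 6888, of which 1 was shared with the 6, and 6 without normal lung 6893, of which 3 were shared.

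**Figure D2:**
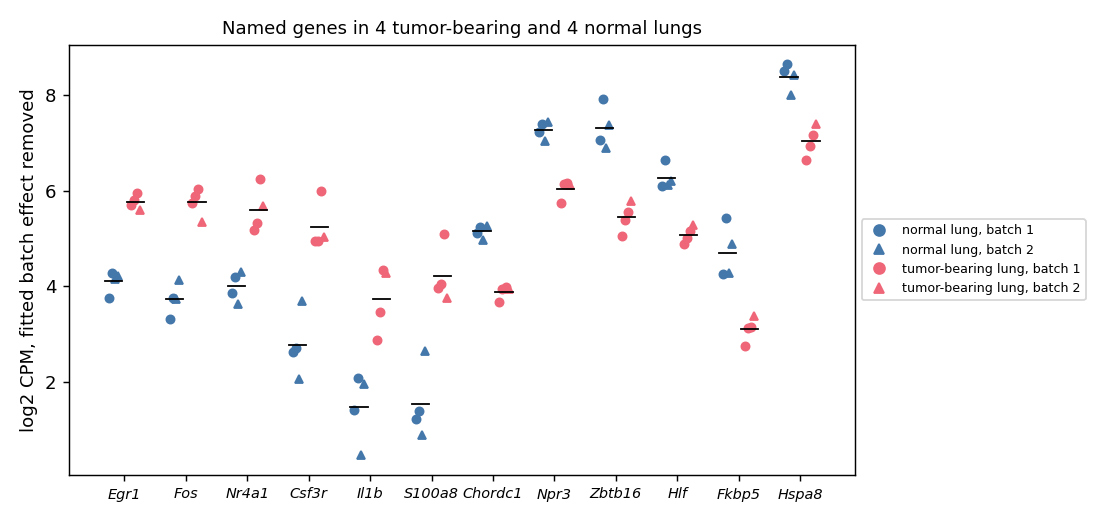
Expression (log2 CPM with the fitted batch effect removed, vertical axis) of 12 named genes in the 4 tumor-bearing and 4 normal lungs; circles are batch 1, triangles batch 2 and bars group means. Fos and Egr1 passed the test as higher and Chordc1 and Npr3 as lower in tumor-bearing lungs; the other genes shown did not pass it over all genes.

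All 16 measured neutrophil genes had positive log2 fold changes, with medians of 1.42 within batch 1 and 1.15 within batch 2, and the group was higher (adjusted p = 1.38e-14, and adjusted p = 0.526 with an estimated correlation). Csf3r, the receptor of granulocyte colony-stimulating factor, had a log2 fold change of 2.46 (SE 0.41), S100a8, a calgranulin subunit, 2.63 (SE 0.53; 1.51 without a batch term), the cytokine Il1b 2.32 (SE 0.44) and Slfn4, an interferon-inducible myeloid gene, 2.52 (SE 0.51). Adjusted over the list alone 10 members were higher. Over all genes edgeR and voom called 0 and DESeq2 called 7, and 11 had an unadjusted p below 0.05 with edgeR. The mean of the group relative to the 10 lung libraries was 0.10 to 1.20 in the tumor-bearing and −0.97 and −0.95 in the normal lungs of batch 1. In batch 2 it was 1.06 in the tumor-bearing lung and −0.70 to 0.27 in the normal lungs. Normal lungs 6886 and 6888 had −0.95 and −0.97 in batch 1 and 0.01 and −0.20 in batch 2.

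Natural killer cell genes were higher as a group (median 0.43; 0.33 and 0.63 within batches 1 and 2, adjusted p = 0.0465, and adjusted p = 0.526 with an estimated correlation), with Nkg7, a cytotoxic granule protein, at 0.88 and the T-box factor Eomes at 0.91. B cell and plasma cell genes were higher (median 0.51; 0.60 and 0.65 within batches, adjusted p = 0.0147, and adjusted p = 0.713 with an estimated correlation), with Fcer2a, a low-affinity IgE receptor, at 0.91. Genes of the interferon response were higher (median 0.23; 0.18 and 0.22 within batches, adjusted p = 0.0342, and adjusted p = 0.713 with an estimated correlation), with the antiviral genes Mx1 at 1.23 and Oas3 at 1.03. Over all genes edgeR and voom called 0 of their 15, 21 and 34 measured members and DESeq2 called 0, 1 and 0. In each 0 passed adjusted over the list alone, and 3, 5 and 4 had an unadjusted p below 0.05. Of these 2, 3 and 4 were higher and 1, 2 and 0 lower, among the lower Rora, a nuclear receptor (−0.36), and Xbp1, a factor of plasma cells (−0.38). The natural killer call was lost without normal lung 6886 (adjusted p = 0.0695), 6887 (0.0762) or 6893 (0.122) and without tumor-bearing lung 6880 (0.10) or 6877 (0.282). The B cell call was lost without normal lung 6888 (0.0918) or 6893 (0.0971) or tumor-bearing lung 6877 (0.0973). The interferon call was lost without normal lung 6887 (0.0559) or 6888 (median 0.11, adjusted p = 0.214) or tumor-bearing lung 6881 (0.12, 0.0890) or 6877 (0.131). In batch 1 alone the natural killer (adjusted p = 0.304), B cell (0.102) and interferon calls (0.163) were all lost.

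Ribosomal protein genes were lower as a group: 41 of 43 had negative values, with medians of −0.51 within batch 1 and −0.26 within batch 2 (adjusted p = 4.83e-21, and adjusted p = 0.526 with an estimated correlation). Examples are Rpl11 (−1.12, SE 0.21), Rps3 (−0.92), Rpl36 (−1.17) and Rpl13 (−0.66), whose many processed copies make single values uncertain. Of its members 25 were lower adjusted over the list alone. edgeR and voom called 0 over all genes and DESeq2 14, and 29 had an unadjusted p below 0.05. Unfolded protein response genes were lower (medians within batches −0.56 and −0.31, adjusted p = 9.62e-08, and adjusted p = 0.526 with an estimated correlation), with Hspa5, the endoplasmic reticulum chaperone BiP, at −0.99 (SE 0.21), the secreted factor Manf at −1.15 (SE 0.23) and Ddit3, the stress transcription factor CHOP, at −0.87. Of 21 members 12 were lower adjusted over the list alone. Over all genes edgeR and voom called 0 and DESeq2 7, with 12 at unadjusted p below 0.05. Mitochondrially encoded genes were lower (medians within batches −0.62 and −0.29, adjusted p = 5.41e-05, and adjusted p = 0.690 with an estimated correlation), with the complex I subunit mt-Nd4 at −0.92 and the cytochrome b gene mt-Cytb at −0.84. Of 13 members 4 were lower adjusted over the list alone. edgeR and voom called 0 over all genes and DESeq2 3, with 7 at unadjusted p below 0.05. Of protein-coding counts, ribosomal protein genes took 0.927 to 0.979% in the normal and 0.701 to 0.787% in the tumor-bearing lungs of batch 1, against 1.80 to 2.56% and 1.80% in batch 2.

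Genes of replication-dependent histones were lower as a group (median −0.38; −0.53 and 0.01 within batches 1 and 2, adjusted p = 0.000121, and adjusted p = 0.713 with an estimated correlation), and the call was lost without normal lung 6886 (adjusted p = 0.229). Hist1h4h stood at −0.52 and Hist1h2bc at −0.49; the near-identical copies of histone genes make single members uncertain. Of 48 members 0 passed adjusted over the list alone. Over all genes edgeR and voom called 0 and DESeq2 1, with 10 at unadjusted p below 0.05.

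Endothelial genes were lower as a group (median −0.22; −0.24 and −0.20 within batches, adjusted p = 0.00531, and adjusted p = 0.690 with an estimated correlation). Without a batch term their median was −0.0375 and the call was lost (adjusted p = 0.430). Among them Gpihbp1, which anchors lipoprotein lipase on capillaries, stood at −0.61, the sialomucin Emcn at −0.54 and Car4, a capillary carbonic anhydrase, at −0.39. Lymphatic and mesothelial genes were lower (median −0.25; −0.47 and 0.11 within batches, adjusted p = 0.0414, and adjusted p = 0.713 with an estimated correlation), with the hyaluronan receptor Lyve1 at −1.10. Alveolar type 1 cell genes were lower (median −0.25; −0.44 and 0.18 within batches, adjusted p = 0.00760, and adjusted p = 0.713 with an estimated correlation), with the caveolar protein Cav1 at −0.64, or −0.97 and −0.02 within batches. Complement and coagulation genes were lower (median −0.14; −0.26 and 0.07 within batches, adjusted p = 0.0175, and adjusted p = 0.713 with an estimated correlation), with Plat, tissue plasminogen activator, at −1.26 and Thbs1, a matrix glycoprotein, at −0.68. Adjusted over the list alone 1 of 26, 1 of 16, 0 of 18 and 1 of 29 members were lower. edgeR and voom called 0 over all genes, DESeq2 called 2, 1, 0 and 2, and 7, 3, 4 and 4 had an unadjusted p below 0.05. The lymphatic call was lost without normal lung 6886 (median 0.16, adjusted p = 0.4001) or tumor-bearing lung 6879 (−0.14, 0.121) or 6880 (−0.16, 0.133), and its median was −0.48 without tumor-bearing lung 6877. It was also lost with all libraries (median −0.15, adjusted p = 0.0710) and with protein-coding genes alone (−0.23, 0.0543). The type 1 call was lost without normal lung 6886 (0.0525) or 6888 (0.0625), and the median was −0.45 without tumor-bearing lung 6877. In batch 2 alone, where 1 tumor-bearing lung stands in its group, the type 1 list passed as higher (median 0.18, adjusted p = 0.0166). The complement call was lost without normal lung 6886 (median −0.000103, adjusted p = 0.265), and its median was −0.26 without normal lung 6888 or tumor-bearing lung 6877. The endothelial median was −0.13 without tumor-bearing lung 6879.

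The 31 immediate early and stress genes moved both ways: adjusted over the list alone 12 were higher and 8 lower, and over all genes edgeR and voom called 2, Fos and Egr1, while DESeq2 called 6 higher and 6 lower. The group was higher by its test (median 0.36, mean 0.11; 0.49 and 0.07 within batches, adjusted p = 0.0465, and adjusted p = 0.786 with an estimated correlation). The members lower adjusted over the list alone were heat shock chaperones. Beside Hspa8 these included Hsph1 at −1.55, Dnaja1 at −1.39, Dnajb1 at −1.12 and Hsp90aa1 at −1.08, which were chosen after their values were seen. The call of the group was lost without normal lung 6887 (adjusted p = 0.175) or 6888 (0.0625) and without tumor-bearing lung 6879 (median 0.19, adjusted p = 0.603) or 6877 (0.266). It was also lost with the length and GC offset (0.26, 0.111), with all libraries (0.27, 0.609) and in batch 1 alone (0.49, 0.241). Clock genes were lower as a group (median −0.19; −0.22 and −0.12 within batches, adjusted p = 0.0130, and adjusted p = 0.690 with an estimated correlation), with the repressors Cry1 at −1.08 and Per2 at −0.79 and the activator Npas2 at 1.88. This call was lost without normal lung 6888 (0.0577). Genes of the acute phase and of glucocorticoid response were lower (median −0.27; −0.48 and 0.15 within batches, adjusted p = 0.0245, and adjusted p = 0.781 with an estimated correlation), with Fkbp5, a cochaperone of the glucocorticoid receptor, at −1.71 (SE 0.29), Angptl4 at −1.16 and Tsc22d3 at −0.71. That call was lost without normal lung 6888 (median −0.00254, adjusted p = 0.218) or 6893 (−0.17, 0.0962) or tumor-bearing lung 6880 (−0.0907, 0.225) or 6881 (−0.11, 0.117). Its median was −0.12 without normal lung 6886 and −0.46 without tumor-bearing lung 6877. Of the 21 acute phase and glucocorticoid genes 7 had positive and 14 negative values. Adjusted over the list alone 1 clock gene was higher and 2 lower of 20, and 3 acute phase and glucocorticoid genes were lower of 21. Over all genes edgeR and voom called 0, DESeq2 called 2 and 3, and 6 and 6 had an unadjusted p below 0.05. Of these 1 and 2 were higher and 5 and 4 lower.

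Of 41 gene lists tested with camera, 15 passed, 5 as higher and 10 as lower. By camera with an estimated correlation 0 passed (3 at unadjusted p below 0.05), and fry, which asks whether a list moves one way on balance, called 0 (7 at unadjusted p below 0.05). The mixed form of fry, which asks whether members differ in either direction, called 23. It does not compare a list with the other genes, and it was not run on other splits of the lungs. The count of lists was 9 without normal lung 6888 and 9 without a batch term. Without a batch term the calls of natural killer (adjusted p = 0.290), B cell (0.0722), interferon (0.0956), clock (0.0970), endothelial (0.430), type 1 cell (0.154), lymphatic (0.254) and complement genes (0.167) were lost. With 1 library per mouse the effect of the tumor differed between batches for some of these 15 lists. They were type 1 cell genes (adjusted p = 3.36e-05), acute phase and glucocorticoid genes (0.00102), histone genes (0.00841), ribosomal protein genes (0.0457) and unfolded protein response genes (0.0463). With all 10 lung libraries normal lungs 6886 and 6888 each enter with 2 libraries. Their adjusted p of this difference were then 1.54e-07, 0.0165, 0.000504, 0.00256 and 0.0569, in the order of these lists. The effect in batch 2 rests on tumor-bearing lung 6877 alone, so that these tests cannot tell a difference between batches from a difference of that mouse. They were run by camera at the preset correlation of 0.01 alone.

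**Figure D3:**
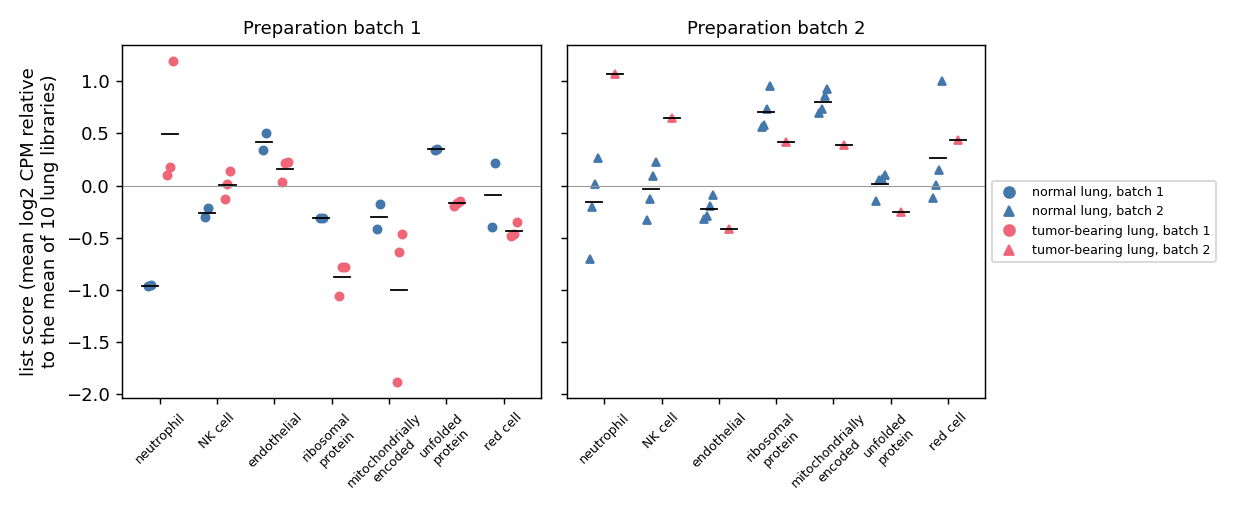
Mean log2 CPM of 7 gene lists relative to the mean of the 10 lung libraries (vertical axis), with batch 1 and batch 2 in separate panels, points for single libraries and bars for group means. Neutrophil scores of the tumor-bearing lungs were 0.10 to 1.20 in batch 1 and 1.06 in batch 2, against −0.97 to −0.95 and −0.70 to 0.27 in the normal lungs.

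The comparison of mammary tumors with tumor-bearing lungs shows how far the 2 tissues of these mice differ. Of measured genes of alveolar type 1 and type 2 cells and of endothelium, 17 of 18, 17 of 22 and 23 of 26 fell in the tumors, and 36 of 36 cell cycle genes and 17 of 29 mammary epithelial genes rose. The endothelial list passed with an estimated correlation (adjusted p = 0.0407) and the others did not (adjusted p = 0.0705, 0.0878, 0.0878 and 0.0878 with an estimated correlation). Sftpc, surfactant protein C of alveolar type 2 cells, stood at 4.67 ± 3.77 CPM in tumors (SD, n = 3) and 4047 ± 2352 in tumor-bearing lungs (SD, n = 4) and fell by 10.48 on the log2 scale (SE 0.88). Birc5, the mitotic protein survivin, stood at 264 ± 66.3 against 2.36 ± 0.663 CPM (SD, n = 3 and 4), a log2 fold change of 6.45 (SE 0.33). Lcn2, an iron-binding secreted protein, stood at 986 ± 68.9 against 11.6 ± 8.09 CPM (SD, n = 3 and 4), a log2 fold change of 5.82 (SE 0.35).

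Among genes higher in tumors, Col2a1, the collagen of cartilage, stood at 324 ± 136 CPM against 0.212 ± 0.378 (SD, n = 3 and 4), a log2 fold change of 10.68 (SE 1.29). Several genes had 0 counts in the 4 tumor-bearing lungs, so that their fold is a lower bound set by 3 counts over the group. They were at least 191-fold higher for Pkp1, a desmosomal plaque protein, 288-fold for the amino acid transporter Slc38a3 and 190-fold for Crabp2, which binds retinoic acid. The bounds of Mup14 and Mup10, 348-fold and 236-fold, are uncertain because major urinary protein genes have near-identical copies. For genes with 1 to 3 counts in these lungs the ratios and their 95% counting intervals were 1199 (332 to 9912) for Tfap2c, a transcription factor of the mammary epithelium, and 1521 (272 to 60111) for the serpin Serpinb5. They were 513 (91.6 to 20331) for Hhipl2, 75.5 (25.4 to 370) for the mucin Muc15 and 1299 (233 to 51382) for Hist1h2ba, whose family has near-identical copies. Pgk1-rs7, a retrogene copy of a glycolytic gene with uncertain reads, stood at 32.1 ± 11.8 against 2.89 ± 4.30 CPM (SD, n = 3 and 4), with a log2 fold change of 10.20 (SE 2.69) after adjustment for batch, far larger than the ratio of these means; it was 3.55 without a batch term and 11.54 in batch 2 alone. Tumor 6880 carried 2 of these values, and without it the ratio of Hist1h2ba was 137 and the bound of Mup10 was 66.6-fold. Without tumor-bearing lung 6880, which held their only count, Serpinb5, Hhipl2 and Hist1h2ba were at least 342-fold, 115-fold and 292-fold higher. The ratio of Hist1h2ba was 2005 without tumor 6881, and that of Muc15 was 48.9 without tumor 6877 and 161 without tumor-bearing lung 6881. Without tumor-bearing lung 6877, 6 of these genes lost their call: Serpinb5, Slc38a3, Mup10 and Pkp1 (adjusted p = 0.9999 each), Hist1h2ba (0.109) and Pgk1-rs7 (0.121). That fit leaves tumor-bearing lungs in batch 1 alone and tumors in batch 2 alone. Batch is then told from tumor through the normal lungs, where Serpinb5, Slc38a3, Mup10 and Pkp1 had 0 counts. Their log2 fold changes in it were 9.84, 10.76, 10.33 and 10.18, so these 4 lost calls do not show smaller differences.

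Among genes lower in tumors, Scgb1a1, the secretoglobin of club cells, stood at 4.74 ± 4.04 against 4788 ± 1677 CPM (SD, n = 3 and 4) and fell by 10.35 (SE 0.85). Sec14l3, a lipid-binding protein, stood at 0.431 ± 0.242 against 632 ± 71.4 CPM (SD, n = 3 and 4) and fell by 10.31 (SE 0.37). With 0 counts in the tumors, Foxa2, a transcription factor of lung epithelium, was at least 290-fold lower, Gpm6a at least 365-fold and Dnah5, an axonemal dynein of cilia, at least 228-fold. Edn3, an endothelin, was at least 170-fold lower, Mlc1 at least 147-fold and S100g, a calcium-binding protein, at least 140-fold. The ratio of lung to tumor was 3860 (693 to 152507) for the complement gene C7 and 1915 (655 to 9290) for the cytochrome Cyp2b10. Myh6, the atrial myosin heavy chain of heart muscle, was at least 1394-fold lower, a value set by tumor-bearing lung 6879 with 681 CPM against 8.19 to 10.8 in the other tumor-bearing lungs, and at least 111-fold lower without it. Without tumor 6880 or 6881, whose depth lowers the floor, each bound of a gene at 0 counts in tumors was lower by a factor of 1.60 or 1.61. The bound of S100g was 84.2-fold without tumor-bearing lung 6877, and without tumor 6881 C7 was at least 802-fold lower and the ratio of Cyp2b10 was 3580. The ratio of C7 was 2407 without tumor 6880. The call of Myh6 was lost without normal lung 6886 (adjusted p = 0.0503) and without tumor 6877 (0.0587), 6880 (0.0554) or 6881 (0.0558). On GRCm38 Sftpc lies on chromosome 14 at 70520949 to 70524081, Scgb1a1 on chromosome 19 at 9083636 to 9087958 and Col2a1 on chromosome 15 at 97975602 to 98004695.

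Of 18 measured genes of alveolar type 1 cells 17 fell and 1 rose (median −7.29, adjusted p = 1.20e-38, and adjusted p = 0.0705 with an estimated correlation). Among them were Clic5, a chloride channel protein (−8.30, SE 0.28), Akap5 (−8.54) and Rtkn2 (−7.42). Of 22 genes of type 2 cells 17 fell and 1 rose (median −5.57, adjusted p = 2.46e-25, and adjusted p = 0.0878 with an estimated correlation). They included the lamellar body protein Lamp3 (−10.16, SE 0.27), the transcription factor Nkx2-1 (−8.71), the phosphate transporter Slc34a2 (−8.88) and the chemokine Cxcl15 (−8.83). Of 19 club and ciliated cell genes 15 fell and 1 rose (median −5.86, or −5.34 with genes at 0 counts set to their bound, adjusted p = 7.22e-15, and adjusted p = 0.0878 with an estimated correlation). They included the retinal dehydrogenase Aldh1a1 (−8.85) and the cytochrome Cyp2f2 (−8.45). Of 26 endothelial genes 23 fell (median −3.87, adjusted p = 4.39e-31, and adjusted p = 0.0407 with an estimated correlation). They included Tmem100 (−8.04, SE 0.36), the tight junction gene Cldn5 (−6.46), Car4 (−6.39) and the angiopoietin receptor Tek (−5.54). Adjusted over the list alone the counts were 17, 17, 16 and 23 lower and 1, 1, 1 and 0 higher. Of 20 alveolar macrophage genes 16 fell and 3 rose (median −2.72, adjusted p = 1.45e-07, and adjusted p = 0.164 with an estimated correlation). They included Atp6v0d2, a subunit of the vacuolar proton pump (−6.07, or −4.72 without a batch term). The counts were the same adjusted over the list alone. Members of this list also include Car4, of the endothelial list, and Krt19, of the mammary epithelial and lymphatic lists. These lists are therefore not independent of each other. Of 17 red cell genes 10 fell, also adjusted over the list alone (median −3.78, adjusted p = 0.000207, and adjusted p = 0.253 with an estimated correlation), with the globins Hba-a2 at −5.35 and Hbb-bs at −4.83, whose near-identical copies share reads.

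All 36 cell cycle genes rose, also adjusted over the list alone (median 3.32, adjusted p = 8.18e-23, and adjusted p = 0.0878 with an estimated correlation). Among those that rose were Ccnb1, a mitotic cyclin (5.52), the spindle factor Tpx2 (5.26) and thymidylate synthase Tyms (4.42). Of 29 mammary epithelial genes 17 rose and 2 fell, also adjusted over the list alone (median 2.06, adjusted p = 3.52e-07, and adjusted p = 0.0878 with an estimated correlation). The milk protein gene Csn3 rose from 0.993 ± 0.435 to 328 ± 68.4 CPM (SD, n = 4 and 3; log2 fold change 8.16, SE 0.56) and osteopontin, Spp1, from 40.8 ± 28.1 to 1688 ± 345 CPM (SD, n = 4 and 3; 4.66), while the keratin Krt19 fell by 4.28. Of 28 genes of hypoxia and glycolysis 20 rose and 3 fell, also adjusted over the list alone (median 1.45, adjusted p = 3.52e-07, and adjusted p = 0.134 with an estimated correlation). Among those that rose were the oxygen sensor Egln3 (7.24), the glucose transporter Slc2a1 (3.53) and phosphoglycerate mutase Pgam1 (2.997), while the vascular growth factor Vegfa fell by 2.59. Of 34 interferon gamma and antigen presentation genes 25 rose and 1 fell, or 26 and 1 adjusted over the list alone (median 1.42, adjusted p = 1.63e-07, and adjusted p = 0.372 with an estimated correlation). Among those that rose were the immunity GTPases Iigp1 (3.99) and Irgm1 (2.85) and the immunoproteasome subunit Psmb8 (3.27). Of 25 monocyte genes 13 rose and 4 fell, or 14 and 4 adjusted over the list alone (median 1.00, adjusted p = 0.0190, and adjusted p = 0.372 with an estimated correlation). The transglutaminase F13a1 stood at 3.56, Cd14, a lipopolysaccharide coreceptor, at 2.42 and Ace, angiotensin-converting enzyme, at −4.22.

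Further lists passed as higher in tumors, namely replication-dependent histones (47 of 50 rose, 49 adjusted over the list alone; median 4.30, adjusted p = 4.23e-34), ribosomal proteins (43 of 43 rose, also adjusted over the list alone; median 1.78, adjusted p = 1.93e-12) and the interferon response (18 of 36 rose, also adjusted over the list alone; median 1.31, adjusted p = 0.000752). Also higher were genes of the unfolded protein response (14 of 21 rose and 2 fell, also adjusted over the list alone; median 1.08, adjusted p = 0.00120) and mitochondrially encoded genes (8 of 13 rose, 10 adjusted over the list alone; median 1.15, adjusted p = 0.00886). With an estimated correlation their adjusted p = 0.0878, 0.372, 0.525, 0.372 and 0.515. Lower in tumors were lymphatic and mesothelial genes (14 of 16 fell, also adjusted over the list alone; median −4.25, adjusted p = 3.07e-09), angiogenesis genes (18 of 26 fell and 2 rose, also adjusted over the list alone; median −1.88, adjusted p = 3.28e-08) and smooth muscle genes (13 of 18 fell and 2 rose, 14 and 3 adjusted over the list alone; median −2.16, adjusted p = 3.81e-05). Also lower were platelet genes (12 of 19 fell and 1 rose, 16 and 1 adjusted over the list alone; median −3.18, adjusted p = 0.000752) and clock genes (10 of 20 fell and 4 rose, 10 and 5 adjusted over the list alone; median −1.52, adjusted p = 0.00414). With an estimated correlation their adjusted p = 0.0878, 0.0878, 0.0880, 0.479 and 0.247.

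edgeR tested 18297 genes in 11 libraries and called 8471, 4128 higher and 4343 lower in tumors, and 21 of 42 lists passed camera, of which 1, the endothelial list, passed with an estimated correlation. By fry 29 lists passed, 12 higher and 17 lower, with the 21 among them. All tumors were prepared in batch 2 with 1 of the 4 tumor-bearing lungs. In batch 2 alone 7096 genes passed, 6566 of them shared, if that lung is taken to vary like the libraries of the other groups. There the monocyte list (adjusted p = 0.0559), Hist1h2ba (0.0535), Mup10 (0.0531) and Myh6 (0.163) did not pass. With the mouse as a block 7810 genes passed, and 4441 with the block and a batch term. On TPM 5322 passed, 4142 higher and 1180 lower.

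**Figure D4:**
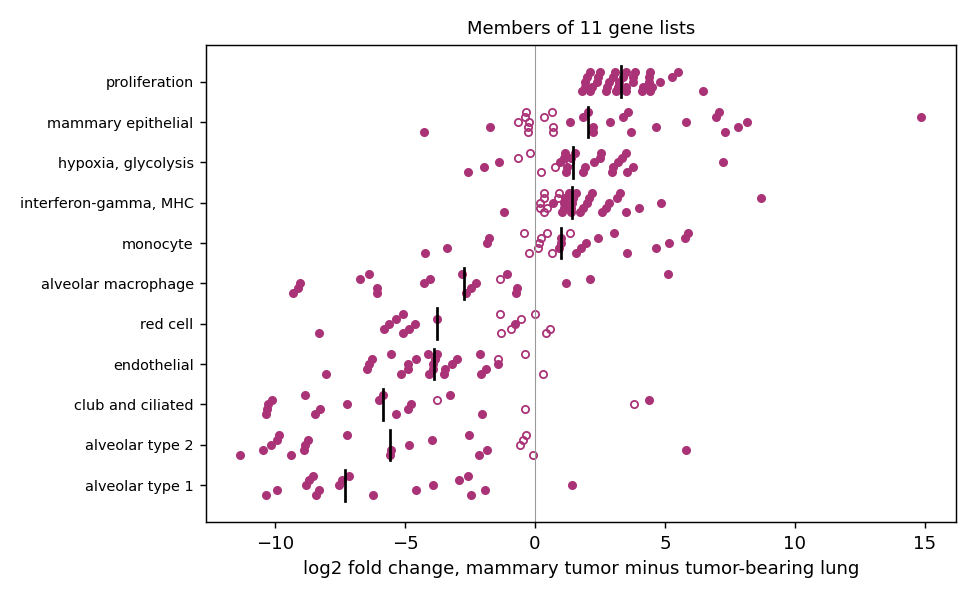
Log2 fold change of mammary tumors minus tumor-bearing lungs (axis of values) for the measured members of 11 gene lists; filled points passed the threshold over all genes, open points did not, and bars are medians. Medians ran from −7.29 for alveolar type 1 cell genes to 3.32 for cell cycle genes.

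The comparison of mammary tumors with normal lungs sets the same tumors against lungs of mice without a tumor. The lung epithelial genes Lamp3, Sftpc and Scgb1a1 fell in tumors and Tfap2c, a transcription factor of the mammary epithelium, rose. Tfap2c rose to 50.0 ± 15.0 CPM in tumors (SD, n = 3) from 0.305 ± 0.514 in normal lungs (SD, n = 4), a log2 fold change of 11.72 (SE 0.94) after adjustment for batch, far larger than the ratio of these means; it was 7.33 without a batch term and 10.64 in batch 2 alone. Lamp3 stood at 0.144 ± 0.0213 against 199 ± 15.2 CPM (SD, n = 3 and 4) and fell by 10.48 (SE 0.26). Sftpc fell by 11.00 (SE 0.89) from 6708 ± 2398 CPM (SD, n = 4) in normal lungs. Scgb1a1 fell by 10.37 (SE 0.84) from 5192 ± 674 CPM (SD, n = 4) and Sec14l3 fell by 10.32 (SE 0.36) from 619 ± 92.0 CPM (SD, n = 4).

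With 0 counts in the normal lungs, Serpinb5 was at least 499-fold higher in tumors, Cdhr1, a cadherin-related protein, at least 423-fold and Slc38a3 at least 283-fold. Mup10 was at least 233-fold higher, Pkp1 at least 188-fold and Ubd, a ubiquitin-like modifier, at least 117-fold. The ratios with their 95% counting intervals were 3093 (555 to 122218) for the T-box factor Tbx15 and 274 (75.2 to 2267) for Alkal2, a ligand of receptor tyrosine kinases. With near-identical copies of their families, they were 427 (146 to 2073) for Hist1h2ba and 343 (117 to 1668) for Mup14. Pgk1-rs7, a retrogene copy, stood at 32.1 ± 11.8 against 0.223 ± 0.445 CPM (SD, n = 3 and 4), with a log2 fold change of 13.23 (SE 2.32) after adjustment for batch, far larger than the ratio of these means; it was 7.15 without a batch term and 4.53 in batch 2 alone. With 0 counts in the tumors, S100g was at least 317-fold lower, Gpm6a at least 291-fold, Upk3b, a uroplakin of the mesothelium, at least 262-fold, Foxa2 at least 250-fold, Edn3 at least 204-fold and Bex4 at least 126-fold. The ratio of lung to tumor was 3636 (652 to 143656) for C7 and 2247 (769 to 10898) for Cyp2b10. Without tumor 6880 the ratio of Hist1h2ba was 44.9, the bound of Mup10 65.6-fold and the ratio of C7 2267. Without tumor 6881 the ratio of Hist1h2ba was 659, that of Cyp2b10 4200 and C7 was at least 755-fold lower. Without either of these tumors each bound of a gene at 0 counts in tumors was lower by a factor of 1.60 or 1.61. Tbx15 was at least 784-fold higher without normal lung 6888, Alkal2 at least 132-fold higher and Upk3b at least 150-fold lower without normal lung 6886. edgeR called 9014 of 18297 genes, 4490 higher and 4524 lower. With the batch 2 libraries of normal lungs 6886 and 6888 in place of those of batch 1, so that these tumors and normal lungs share 1 batch, 10389 genes passed and 8761 of them were shared. In batch 2 alone 10708 genes passed and 8710 of them were shared. On TPM 6522 passed, 2643 higher and 3879 lower, and with the length and GC offset 9298, 5277 higher and 4021 lower.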

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

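The tests on length and GC content and on other splits of the samples were written before their results were seen. Those on the batch 1 libraries alone, on blood, on splits within batches and on splits with fry were chosen after the result was seen. The test on the batch 1 libraries alone asked for at least 2 tumor-bearing lungs of batch 2 to argue against that explanation. Batch 2 holds 1, so the test could not have closed it for any pattern. The interaction of batch and group was fitted over 10 lung libraries, in which normal lungs 6886 and 6888 each enter with 2, and again with 1 library per mouse. In this section the SE of a median was taken over the genes of the pattern, as if they were independent. Genes of a list can vary together, so these SE do not measure the spread between mice. The readings of the length and GC offset rest on them and leave out that spread.

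Neutrophil genes were higher in tumor-bearing lungs by camera (median log2 fold change 1.23, SE 0.28 over genes). Their adjusted p was 0.526 with an estimated correlation and 0.173 with fry. Over all genes edgeR called 0 of them, with 11 at unadjusted p below 0.05, voom called 0 and DESeq2 called 7. All 16 measured genes had counts in normal lungs and 5 also belong to other lists, and the most abundant, as means in tumor-bearing and normal lungs, were Hdc (46.5 and 29.0 CPM), Lrg1 (39.8 and 21.2), Csf3r (38.5 and 7.32) and S100a9 (35.2 and 10.1). An offset for gene length and GC left the median at 1.21 (SE 0.29), which argues against such a bias as the whole cause, and more blood in these lungs is argued against by the red cell genes, with a median of −0.13 and an upper quartile of 0.12 over 17 genes. A difference in the batch 1 libraries alone stays open, with an interaction p of 0.372 for batch and group (0.549 with 1 library per mouse) and the 1 tumor-bearing lung of batch 2 at a score of 1.06 against −0.70 to 0.27 in its batch. A higher share of neutrophils or their precursors in the lung of tumor-bearing mice may be the source and stays an untested hypothesis. Granule genes of bone-marrow precursors did not pass by camera (median 0.41, 6 genes, adjusted p = 0.453), with 0 at unadjusted p below 0.05. The red cell genes cannot tell whether the blood itself held more neutrophils. For the neutrophil list exact permutation within batches gave p = 0.0333, the smallest it can give, and an adjusted p of 0.342 over 41 lists.

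Genes of ribosomal proteins, the mitochondrial genome and the unfolded protein response were lower in tumor-bearing lungs by camera (median fall 0.46, SE 0.05, 77 genes), with adjusted p of 0.526, 0.690 and 0.526 with an estimated correlation, and edgeR called 0 of them over all genes, with 29, 7 and 12 at unadjusted p below 0.05, voom 0 and DESeq2 14, 3 and 7. The offset for length and GC left a fall of 0.37 (SE 0.05), which argues against that bias as the whole cause. A difference in the batch 1 libraries alone stays open, with an interaction p of 8.88e-07 (0.000153 with 1 library per mouse) and mean falls of 0.57 in batch 1 and 0.30 in batch 2, where the 1 tumor-bearing lung, at a score with the sign turned of −0.23 against −0.61 to −0.47, lay beyond its batch in the direction of the fall. The share of Rn7s1 and of the most abundant gene models also differed between the groups in batch 1, so a difference in RNA quality or preparation of those libraries could not be told apart from an effect of the tumor.

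In the list of immediate early and stress genes, split by name after the values were seen, heat shock genes tended lower and the rest higher (median 0.76 with the sign of heat shock genes turned, SE 0.14, 31 genes), while the list as a whole had an adjusted p of 0.786 with an estimated correlation and edgeR and voom called Fos, Egr1 and no heat shock gene over all genes, with 8 members lower at unadjusted p below 0.05 and 6 called lower by DESeq2. With the length and GC offset the median was 0.68 (SE 0.15), a move too near the bound to exclude a part of that bias. A difference in the batch 1 libraries alone stays open (an interaction p of 0.00212, or 0.0141 with 1 library per mouse, with 0.98 in batch 1 and 0.58 in batch 2, where the 1 tumor-bearing lung scored 0.23 against −0.56 to −0.15). These medians and p use signs set after the values were seen, so they are no independent support for the pattern. The unsplit list had an interaction adjusted p of 0.894 by camera with 1 library per mouse. Both sets of genes respond quickly to stress, so a difference in the handling of tissue and a response to the tumor may each be a source, and neither was tested.

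For the 6 genes between tumor-bearing and normal lung, chance could not be excluded by other splits of the 8 lungs, as 2 of 35 splits gave as many. The highest other split gave 14, with normal lungs 6886 and 6888 and tumor-bearing lungs 6880 and 6881, all of batch 1, against the rest. The fit adjusts for batch, so this split in effect sets tumor-bearing lung 6879 against the other lungs of batch 1. The 35 splits move lungs across batches. Among the 30 that keep the size of each group in each batch, the real one alone gave as many genes and the highest other gave 2, while 10 gave as many lists as the real one and the highest gave 21. The gene counts within batches 1 and 2 were 39 and 8. For the 15 lists chance could not be excluded, with 13 of 35 splits as high and a highest of 21. For the 8471 and 9014 genes of the tumor comparisons chance was excluded, with 1 of 35 splits each, the real one, and highest others of 3 and 14. Each other split puts tumors and lungs together in a group, so this shows that the tissues differ and no more. Among the 8 splits that part as many pairs of the same mouse the highest other was 3. For the 21 lists of tumors by camera chance could not be excluded by their count, with 14 of 35 splits as high and a highest of 26, also among the 8 that part as many pairs, so that this count is reached by splits without regard to tissue. By fry chance was excluded for the 29 lists of tumors, which hold these 21, with 1 of 35 splits, the real one, and a highest other of 1. Here too each other split puts tumors and lungs together in a group, so this shows no more than that the tissues differ. Among the 8 splits that part as many pairs the highest other was also 1, but 8 splits are too few to exclude chance. By fry the real split of the 8 lungs gave 0 lists and the highest other 3.

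Single libraries stood far from the other 3 of their group in 17 of 267 groups of 4 (6.37%), where chance alone gives about 1 in 20. On the log2 CPM scale with the batch effect removed, tumor-bearing lung 6879 had Csf3r at 5.99 (nearest other 5.03), Car4 at 5.61 (5.65), Ccl21a at 4.52 (5.02), C1ra at 4.73 (5.34) and Tmem100 at 7.18 (7.73). Tumor-bearing lung 6881 had Chordc1 at 3.67 (3.94) and Npr3 at 5.74 (6.12). Sec14l3 was at 8.97 in tumor-bearing lung 6880 (9.31) and Krt19 at 6.67 in tumor-bearing lung 6877 (6.36). Among normal lungs Thbs1 was at 8.16 in 6886 (7.47), Manf at 5.30 in 6887 (5.99) and mt-Nd2 at 8.53 in 6888 (7.97). Of list scores, taken as means of log2 CPM relative to the 8 lungs after the batch effect was removed, the unfolded protein score was 0.0240 in normal lung 6887 (nearest other 0.25), the mitochondrial score 0.47 in normal lung 6888 (0.24) and the ribosomal protein score −0.44 in tumor-bearing lung 6879 (−0.18). Tumor-bearing lung 6877, the only one of batch 2, had 37.8% of its counts on Rn7s1 (nearest other 10.3%) and 3.40% of its protein-coding counts on globin genes (nearest other 1.13%).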

How the results depend on the processing

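The length and GC offset, protein-coding genes alone, DESeq2 on the genes of the edgeR filter and, for the tumors, batch 2 libraries alone were chosen after the data were seen. For tumor-bearing against normal lung, where 6 genes passed, the count was 275 without a filter, 390 with DESeq2 and its own filter, 399 with DESeq2 on the same genes, 90 on TPM, 42 with all libraries, 41 with all libraries and mouse as a random block, 39 in batch 1 alone, 2 with repeats summed per mouse (1 shared with the 6), 1 without a batch term (1 shared) and 1 with the batch 2 library of repeated mice (0 shared). It ran from 0 to 221 with 1 mouse left out. It was 4 to 8 with other scaling factors, a CPM filter, voom, batch 2 alone, protein-coding genes and the length and GC offset. The 15 lists became 9 without a batch term, 9 to 18 with 1 mouse left out, 0 with an estimated correlation and 0 with fry. In batch 2 alone, with 1 tumor-bearing lung and the genes that pass the filter there, the test of 6 lists turned its direction. The medians of 5 also changed sign, to acute phase 0.0906, alveolar type 1 cells 0.18 (passing as higher, adjusted p of 0.0166), lymphatic 0.11, complement 0.0649 and histones 0.0217, and that of immediate early genes stayed positive at 0.0725. Of the named genes, Ighd (−0.0209), Ddx58 (−0.19) and Ifih1 (−0.18) changed sign on TPM, and Pdpn with the batch 2 library of repeated mice (0.11) and in batch 2 alone (0.10). The count of tumors against tumor-bearing lungs, 8471, was 5322 on TPM, 5530 with these groups alone, 7810 with mouse as a block and 4441 with block and batch term. It was 6444 to 8375 with 1 library left out, where the other tissue of the same mouse stays in. The 21 lists of this comparison became 1 with an estimated correlation and 29 with fry and stayed at 22 to 24 with 1 library left out. The count of tumors against normal lungs, 9014, ran from 7517 to 9100 with 1 library left out, and no alternative moved it by over 1.5 times. Among results for named genes, 1444 of the lung comparison kept direction and side of the threshold, 132 passed newly, 58 no longer passed and 5 changed sign. Among results for its lists 174 kept both, 75 no longer passed and 6 turned direction. For tumors against tumor-bearing lungs 1855 results for genes kept both and 30 no longer passed, and 209 and 11 for lists. Against normal lungs 641 results for genes kept both and 4 no longer passed. The median of all genes stood at −0.23 on TPM for the lungs, and for tumors against tumor-bearing lungs at −0.10, at −0.24 with upper-quartile factors (3606 higher, 4857 lower) and at 0.04 with the length and GC offset (4794 higher, 3913 lower). Against normal lungs it was −0.14 with upper-quartile factors and 0.11 with the offset (5277 higher, 4021 lower), and on TPM 2643 were higher and 3879 lower. The offset by effective length was not run, since it moves nothing. The cause was not tested. Depth limits genes with few counts, whose folds are bounds or wide ratios.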

Other observations

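The test on tumor RNA in the lungs was chosen after the result was seen. Genes tied to the premetastatic niche went both ways in tumor-bearing lungs: the 27 measured genes had a median of −0.05 and a mean of 0.23, and the list did not pass (adjusted p = 0.576). Adjusted over the list alone 5 were higher and 2 lower. edgeR and voom called 0 over all genes, DESeq2 called 4 as higher, and 7 had an unadjusted p below 0.05 with edgeR. Il1b (2.32), S100a8 (2.63), the calgranulin S100a9 (2.67), the gelatinase Mmp9 (1.51) and the integrin Itga4 (0.52) had positive values, and Thbs1 (−0.68) and the sphingosine phosphate receptor S1pr1 (−0.47) negative ones. S100a9, Mmp9, Itga4 and S1pr1 were chosen after their values were seen. Monocyte genes had a median of 0.14 (adjusted p = 0.0587), T cell genes 0.24 (0.0880), platelet genes 0.36 (0.0850), alveolar macrophage genes −0.12 (0.0850), smooth muscle genes −0.15 (0.0880), angiogenesis genes −0.07 (0.0880) and type 2 cell genes −0.13 (0.0760). Type 2 cell genes had medians of −0.43 in batch 1 and 0.26 in batch 2, from fits that hold both libraries of normal lungs 6886 and 6888. Differences between batches were tested by camera at the preset correlation alone. That of type 2 cell genes passed with 1 library per mouse (adjusted p = 5.26e-06). So did the differences between batches of red cell (0.000316), mammary epithelial (0.00102), alveolar macrophage (0.00129), interferon gamma and antigen presentation (0.0114), T cell (0.0119), inflammatory cytokine (0.0119) and monocyte genes (0.0257), each with tumor-bearing lung 6877 alone in batch 2. Heart and skeletal muscle genes did not (0.160), although they passed with both libraries of normal lungs 6886 and 6888 (0.0317), and red cell genes did not pass there (0.0543).

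Heart and skeletal muscle genes had a median of 1.64 in tumor-bearing lungs (2.12 and −1.82 within batches) and did not pass (adjusted p = 0.138). Their score was 2.59 in tumor-bearing lung 6879 and 2.26 in the batch 2 library of normal lung 6886, whose batch 1 library had −0.54; other lung libraries had −0.76 to −0.11. Adjusted p of the remaining lists in the lung were 0.115 for interferon gamma and antigen presentation, 0.138 for lipid genes, 0.453 for hypoxia, 0.453 for granule precursors, 0.461 for the cell cycle, 0.472 for fat, 0.494 for inflammatory cytokines, 0.494 for interstitial macrophages, 0.557 for red cells, 0.576 for thymus, 0.576 for dendritic cells, 0.592 for mesenchymal transition, 0.6249 for club and ciliated cells, 0.684 for type 2 immunity, 0.819 for checkpoints, 0.826 for mammary epithelium and 0.839 for fibroblasts.

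In tumors against tumor-bearing lungs, lists that did not pass camera at the preset correlation held genes past the threshold. Adjusted p of lists in this paragraph are those of camera unless fry is named. Among fibroblast genes (7 higher and 12 lower of 28, adjusted p = 0.0552) Timp1 rose by 4.30 and Tcf21, a transcription factor of lung fibroblasts, fell by 9.91. Among interstitial macrophage genes (8 higher and 2 lower of 15, 0.0540) the complement gene C1qa rose by 3.28, and among inflammatory genes (10 higher and 5 lower of 28, 0.207) the monocyte chemokines Ccl2 and Ccl7 rose by 5.89 and 5.76. Among neutrophil genes (2 higher and 10 lower of 18, 0.0987) S100a9 fell by 4.57 and Acod1, which makes itaconate, rose by 7.30. Among genes of the mesenchymal transition (8 higher and 8 lower of 23, 0.351) Twist1 rose by 8.98 and Zeb1 fell by 3.17. These genes were chosen after their values were seen. By fry the fibroblast (adjusted p = 0.0115), interstitial macrophage (0.00416), inflammatory (0.00271) and neutrophil lists (0.0151) did pass. So did those of eosinophils and mast cells (2.26e-05), type 2 immunity (0.0104), heart and skeletal muscle (0.0307) and immediate early genes (0.0307). Adjusted p of the other lists were 0.0552 for heart and skeletal muscle, 0.0856 for eosinophils and mast cells, 0.0987 for fat, 0.161 for immediate early genes, 0.372 for checkpoints, 0.463 for the acute phase, 0.469 for the premetastatic niche, 0.733 for type 2 immunity, 0.738 for granule precursors, 0.774 for natural killer cells, 0.851 for lipid genes, 0.890 for complement, 0.898 for B cells, 0.971 for T cells, 0.981 for thymus and 0.991 for dendritic cells. In acute phase genes the median was −0.45 and the mean 0.30.

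Tumor RNA might be present in tumor-bearing lungs. The test took 24 protein-coding genes with at least 20 CPM in tumors whose mean over normal and tumor-bearing lungs was below 1% of the tumor level. Tumor-bearing lungs entered this choice, so genes raised in them by tumor RNA could be left out. Each lung library was compared with the tumor level. Lungs stood at 0.207 to 0.600% of it, with 0.600% in tumor-bearing lung 6877 and 0.430% in normal lung 6886. The one-sided exact permutation within batches gave p = 0.233 over 30 arrangements, of which the smallest possible is 0.0333. The hypothesis stays open in both directions, since the lung libraries are few and this p excludes nothing.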
